A study of Homo sapiens with 14 samples.

How the data were processed

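Total RNA from 14 tumours grown in mice from MDA-MB-231 cells was labelled with biotin and hybridised to Illumina bead arrays, 1 array per tumour, per the labels. Per the labels, 7 tumours came from mock-transfected cells and 7 from cells transfected with COMP, and the mice were 20 weeks old. The submitters' design text calls the arrays mouse arrays, while the probe definitions in the deposited table are those of Homo sapiens. The arrays were therefore read as human. Groups and replicate numbers were taken from the sample titles.

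The scanner table that the authors deposited holds, per the file headers, an average bead signal intensity and a detection p-value for each of 47323 probes on each array. These intensities were neither background-subtracted nor scaled between arrays. The detection p-value was deposited per probe and array, in steps set by the negative control beads. A second deposited table holds the authors' processed intensities of the same arrays. Its column medians lay between 110.33 and 110.35, the lower quartiles between 102.55 and 102.57 and the upper quartiles between 159.31 and 159.33, and the 99th percentile was 5927.96 on every array. The arrays had thus been brought to nearly 1 distribution on a linear scale, and no background subtraction was visible in the lower quartiles. Its direction and scale were read by setting each column against the scanner signals of its own array, where Spearman's rho was 1, against 0.8657 at most for any other array. The software behind both tables is not given in the sources used here.

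The scanner intensities were background-corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the background level inferred from the detection p-values, and were then on a log2 scale. The offset reduces the fold change of dim probes. A probe was kept when its detection p was under 0.05 on at least 7 of the 14 arrays, which 18478 probes met, and 17543 of these had a gene symbol. For a gene with several kept probes the probe with the highest mean was used, which left 13511 genes. Among the genes past the threshold, 212 had several kept probes. In 13 of these a further probe had the opposite sign, 2 of them with an unadjusted p under 0.05. Gene names were updated with the RefSeq genes of assembly GRCh38.p14. By accession 27607 probes were named, by a current symbol 3387 and by an older symbol 1395, while 11664 kept the symbol of the file and 3270 had none. That assembly served for names and for the order of genes along chromosomes only, since the deposited tables name no genome build.

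The comparison of COMP with control tumours was fitted with lmFit and eBayes of limma on group alone, over all 14 arrays, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 24 pathway lists and 9 cell type lists were written before the data were examined. So were the tests of genes and of these lists, the rule for naming genes and all alternatives but 1. The segment step and the tests described below as chosen afterwards were not. Lists were tested with camera of limma, two-sided, with a preset inter-gene correlation of 0.01 and again with a correlation estimated for each list, adjusted over the pathway lists and over the cell type lists. Cell type lists were tested on 30783 genes without the detection filter, since transcripts of other cells were expected near background. The named genes are COMP, the 12 genes with the largest rise and the 12 with the largest fall past the threshold (symbols of uncharacterised loci left out), up to 4 members past the threshold in each list with the smallest p (or the member with the smallest p where none passed), and MMP9, MMP2, VEGFA, HSPA5, DDIT3, LDHA and THBS1. Genes below the detection filter were taken from the fit without it. A probe detected on no array of a group got no fold.

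The genes were also placed in chromosome order, and their log2 fold changes were divided into segments of at least 15 genes by optimal partitioning with a penalty of 5, fold changes being limited to 1 in either direction. A segment was called shifted when its median differed by more than 0.2 from the median of all genes. This step and its parameters were chosen after the data had been seen.

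The procedure was tested on simulated data for COMP against control over 13511 genes. It recovered 57.1% of the genes changed 1.5-fold, 87.1% of those changed 2-fold and 98.3% of those changed 4-fold, with 6 false calls among 13311 unchanged genes. A shifted list was called in 20 of 20 simulations, with 2 false calls in all among 19 other lists. The genes were simulated independently of each other, whereas the estimated correlation reached 0.431 in the cholesterol list. The rate of false calls therefore need not hold for the real lists. The segment step recovered 240 of 240 shifted genes, also with independent genes and with larger shifts than most segments called below.

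Alternatives were no background correction, median centring in place of quantile normalization, the authors' processed intensities, a stricter detection filter (p under 0.01 on all 14 arrays) and none, the mean of a gene's probes, every kept probe, an intensity trend with robust estimation, array weights, the replicate number as a block, a 1.5-fold minimum, an estimated correlation and leaving out each tumour in turn. Leaving out genes of shifted segments was added after seeing the data. Probes without a gene symbol were left out of the gene-level fit. The values of 2 genes that the naming rule takes are not reported here, and both stay in the counts. The number of arrays limits the precision of every value.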

Results

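Gene expression was measured in 14 xenograft tumours of MDA-MB-231, a human triple-negative breast cancer cell line, grown in mice. Control tumours (n = 7) came from mock-transfected cells and COMP tumours (n = 7) from cells transfected with cartilage oligomeric matrix protein (COMP), a secreted glycoprotein of the cartilage and tendon matrix. The single comparison asks which transcripts differ when the cancer cells carry COMP, a gene that the series links to the growth and spread of breast cancer. Between 18660 and 19828 probes were detected per array. COMP arrays had 18998 ± 327.1 detected probes (SD, n = 7) and control arrays 19415 ± 342, a difference with p = 0.0402 in a two-sided exact permutation test and 0.0804 after Benjamini-Hochberg adjustment over 2 tests. The median signal was 113.8 ± 9.31 and 108.9 ± 11.6, respectively (exact permutation p = 0.392, adjusted 0.392). Any 2 arrays correlated at 0.960 or more across the 13511 tested genes after normalization. The labels do not say whether the tumours grew in separate mice or how many transfected populations were injected. The p-values therefore measure the spread between these tumours and not between independent transfections.

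The COMP transcript itself was detected in none of the 7 control tumours and in 2 of the 7 COMP tumours, replicates 2 and 5, where its normalized log2 signal was 5.79 and 6.13. The other 5 COMP tumours lay between 4.31 and 4.51, beside a control mean of 4.40 ± 0.05. The difference rests on these 2 tumours and did not pass in limma (adjusted p = 0.519), so no fold is given. The array has 1 probe for COMP and the deposited tables do not say where in the gene it lies. Its value therefore checks no label.

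MAGEC2, a cancer-testis antigen gene, showed the largest fall of all genes in the main fit. Its log2 signal was 11.39 ± 0.42 in control and 4.99 ± 0.49 in COMP tumours (SD, n = 7), where 4 of 7 arrays detected it, and it fell by 6.40 ± 0.22 (SE), or 84.5-fold (limma, Benjamini-Hochberg adjusted p = 4.03e-12). The size of this fall depends on the background level, with log2 differences from -6.40 to -4.51 over the processing settings, and a further MAGEC2 probe differed by -4.24. Members of another testis antigen family followed, with log2 differences of -4.12 for SPANXD, -3.20 for SPANXE, -2.74 for SPANXA1 and -2.69 for SPANXB1 (limma, adjusted p between 0.00131 and 0.0228). These SPANX genes are nearly identical in sequence, so their probes may not tell them apart, and 2 further SPANXB1 probes differed by -0.55 and -3.02, the latter not passing over all kept probes (limma, adjusted p = 0.0697). KISS1, which encodes a peptide precursor known as a metastasis suppressor, fell by 3.99 ± 0.64. Genes of the contractile cytoskeleton were among the largest falls, with -3.80 for the smooth muscle actin ACTG2 and -3.18 for the actin-binding transgelin gene TAGLN. The noncoding RNA LINC01139 fell by 3.56, and the differences were -2.81 for the decoy receptor IL13RA2, -2.75 for the lipase LIPG and -2.70 for PHGDH, the first enzyme of serine synthesis. ACTG2 was detected in 2 and LINC01139 in 3 of 7 COMP tumours, and their differences ranged from -4.14 to -2.12 and from -3.56 to -1.91 over the processing settings. COMP tumour 4 had a PHGDH signal of 4.97, apart from the other COMP tumours. The call of SPANXB1 was lost without COMP tumour 7 (limma, adjusted p = 0.0503), and that of IL13RA2 without control tumour 2 or 4 or COMP tumour 2 or 3 (adjusted p up to 0.0549). IL13RA2 also lost its call without background correction, with the authors' values, without a detection filter and with an intensity trend and robust estimation (limma, adjusted p between 0.0509 and 0.0785), and its difference ranged from -2.81 to -1.64 over the settings. SPANXA1 and SPANXB1 lost theirs in the last 2 of these settings.

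Uncharacterised loci aside, WDR72 had the largest rise past the threshold in the main fit, from 4.69 ± 0.21 to 7.22 ± 0.38, a log2 difference of 2.53 ± 0.16 (limma, adjusted p = 4.4e-08). The zinc finger gene ZNF467 rose by 2.44 ± 0.43 and ESM1, an endothelial cell-specific proteoglycan also made by tumour cells, by 2.43 ± 0.58. The cystatin gene CST2 rose by 1.91, RFPL4A by 1.88, VSTM2L by 1.88 and PLD5 by 1.85. The G protein-coupled oestrogen receptor GPER1, in a shifted segment, rose by 1.82. Further GPER1 probes differed by 1.72 and 0.23, the latter not passing over all kept probes (limma, adjusted p = 0.4399). ADIRF rose by 1.79, the epithelial transcription factor SPDEF by 1.79, and the solute carriers SLC37A2 and SLC4A11 by 1.65 each. WDR72 and ZNF467 were detected in 2 of 7 control tumours, VSTM2L in 3 and PLD5 in 1, so their fold changes depend on the background level, and the WDR72 difference ranged from 1.08 to 2.57 over the processing settings. The ranges were 1.14 to 2.5 for ZNF467, 1.42 to 2.49 for ESM1, 0.993 to 1.95 for CST2, 0.858 to 1.92 for RFPL4A, 0.771 to 1.93 for VSTM2L, 0.868 to 1.85 for PLD5, 1.21 to 1.9 for GPER1 and 1.05 to 1.74 for SLC37A2, with the lowest values without background correction. ADIRF ranged from 1.59 to 1.9. Without background correction and with the authors' values ADIRF, ESM1, SPDEF, GPER1, ZNF467 and SLC4A11 differed by more than WDR72. In 6 of 14 fits with 1 tumour left out ESM1 or ZNF467 did so, and the order of the largest rises thus depends on the settings. Control tumour 3 had a PLD5 signal of 6.33 and control tumour 2 a ZNF467 signal of 6.38, each apart from the other controls, and COMP tumour 3 had the lowest WDR72 signal, 6.41. The PLD5 call was lost in 9 and the ADIRF call in 11 of 14 fits with 1 tumour left out (limma, adjusted p up to 0.0988 and 0.0887). The ESM1 call was lost without background correction, with the authors' values, without a detection filter and with an intensity trend and robust estimation (limma, adjusted p between 0.0508 and 0.0587). PLD5 and ADIRF lost theirs in these 4 settings too, PLD5 also with median centring and with the replicate number as a block, and CST2 without a detection filter.

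**Figure D1:**
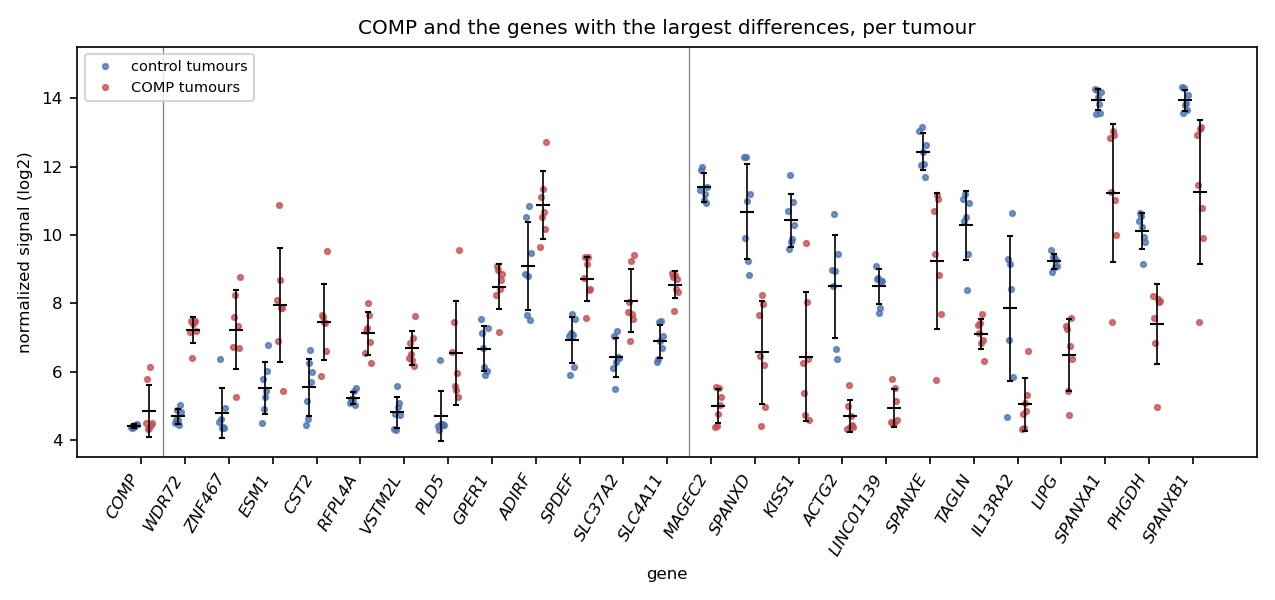
Normalized log2 signal (vertical axis) of COMP and of the 12 genes with the largest rise and the 12 with the largest fall (horizontal axis), with 1 point per tumour, a dash at the mean and bars of 1 SD (n = 7 per group). COMP lies above the other tumours in 2 of the 7 COMP tumours, while MAGEC2 lies near 11.39 in control and near 4.99 in COMP tumours.

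In all, 467 genes were higher and 436 lower in COMP tumours among 13511 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 232 and 256 of these changed at least 1.5-fold. Higher genes made up 51.7% of the calls. With median centring in place of quantile normalization 185 genes were higher and 99 lower, a share of 65.1%, so the balance of the directions depends on the scaling, and 30 of the 67 named genes past the threshold no longer passed. Of these 67, 19 no longer passed without a detection filter and 14 with the replicate number as a block. Without COMP tumour 2 the number of lower genes was 290, and without control tumour 5 the numbers were 561 higher and 552 lower.

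Many changed genes were neighbours on chromosomes. Of 11493 genes placed in order on GRCh38.p14, 1798 (15.6%) lay in 14 segments whose median was shifted, and these held 337 of 818 placed calls (41.2%). The segments were drawn from the same fold changes as the calls, so the higher share of calls in them is partly built in. On chromosome 7, the 143 genes from FAM20C to UBE2D4 had a median log2 difference of 0.56, with 87 called higher and 2 lower. This segment lay between 0.463 and 0.695 over the 7 COMP tumours and between -0.0603 and 0.131 over the 7 control tumours, as medians over the control mean. In 6 of the 14 shifted segments the tumours of the 2 groups did not overlap in this way, and in the other 8 they did. The X chromosome segment from PLCXD1 to ZXDB, for example, ran from -0.352 to -0.262 in COMP and from -0.346 to 0.415 in control tumours. On chromosome 9, the 340 genes from ADAMTSL1 to ASB6 had a median of -0.26, with 66 called lower and 1 higher. Without the genes of all 14 segments 246 genes were higher and 195 lower (limma), an alternative chosen after seeing the data. Of the 903 calls, 566 were still tested in that fit and 441 kept their call, so some calls outside the segments were lost too.

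**Figure D2:**
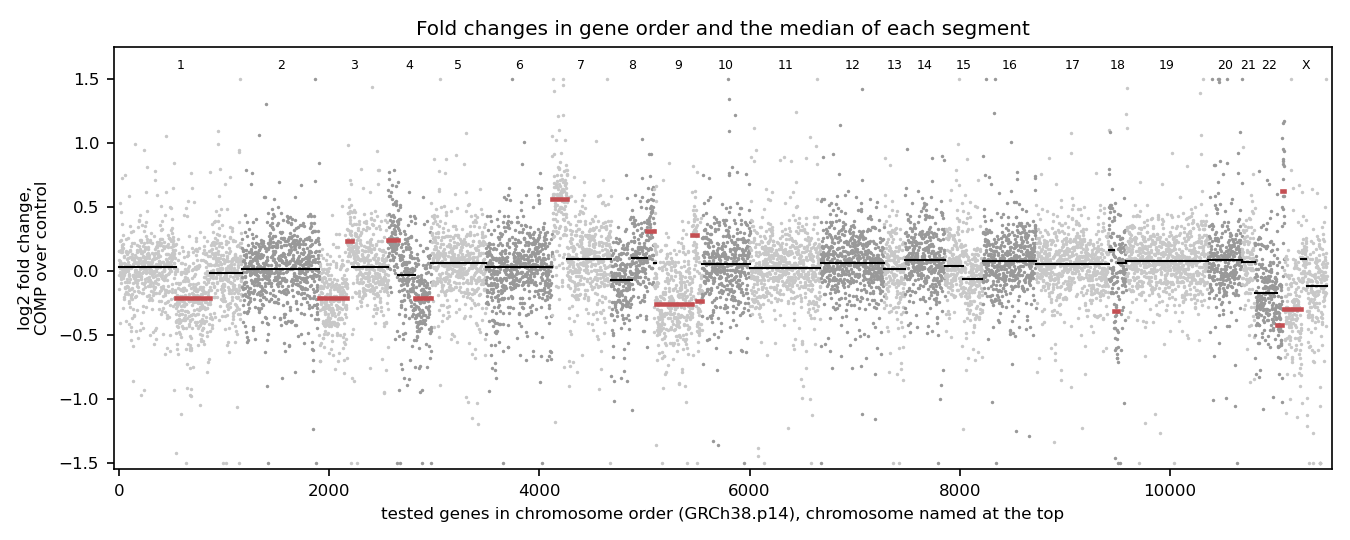
Log2 fold change of COMP over control (vertical axis) for 11493 genes in chromosome order (horizontal axis), with 1 point per gene and points beyond the axis drawn at its edge. Horizontal lines are segment medians, red where shifted, and the one at the start of chromosome 7 lies at 0.56.

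Of the 24 pathway lists, 4 passed camera with the preset correlation, all towards lower expression, and none passed with an estimated correlation. Other splits of the 14 arrays gave as many lists in 53 of 100 cases, the real one included, so the lists are given below as counts of their members. Among genes of the unfolded protein response, which cope with misfolded proteins in the endoplasmic reticulum, 7 of 28 fell and none rose (11 fell when adjusted over the list alone). The chaperone HSPA5 fell by 1.02 ± 0.14, or 2.03-fold (limma, adjusted p = 0.000423). The chaperone cofactor SDF2L1 fell by 0.78, the secreted factor MANF by 0.70 and EDEM1, which acts in degradation of misfolded glycoproteins, by 0.71. With median centring HSPA5 kept its call, and SDF2L1, MANF and EDEM1 lost theirs (limma, adjusted p = 0.072, 0.0969 and 0.0817). DDIT3, the stress-induced transcription factor CHOP, differed by -0.20 ± 0.20 and did not pass. The list median was -0.21 (camera, adjusted p = 8.58e-06, and adjusted p = 0.06 with an estimated correlation). HSPA5, MANF and EDEM1 lie in shifted segments, as do 5 of the 7 genes that fell, and the median without such genes was -0.13 (camera, adjusted p = 0.00217, and adjusted p = 0.398 with an estimated correlation). SDF2L1 was kept there, but its segment on chromosome 22, 215 genes from LOC648771 to TEF, missed the cut of 0.2 narrowly. That segment had a shift of -0.197, with 12 genes called lower and 0 higher. EDEM1 signals stood apart in control tumour 5 (9.31) and COMP tumour 1 (8.05). Of 22 heat shock genes 2 fell (3 over the list alone), CHORDC1 by 0.56 and HSPA4L, in a shifted segment, by 0.61 (limma, adjusted p = 0.00433 and 0.0171). Both lost their call with median centring (limma, adjusted p = 0.305 and 0.264), and their differences ranged from -0.563 to -0.37 and from -0.659 to -0.402 over the settings.

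**Figure D3:**
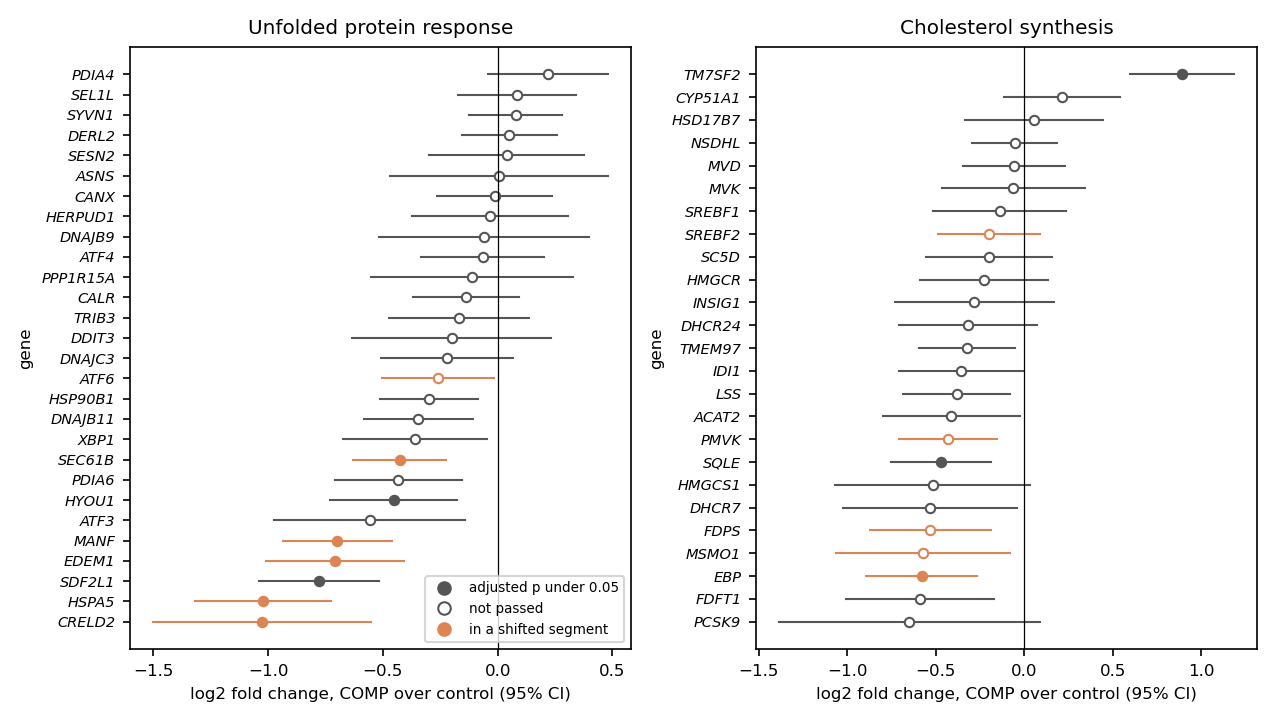
Log2 fold change of COMP over control with its 95% confidence interval (horizontal axis) for tested genes of 2 lists (vertical axes), with 1 gene of the cholesterol list not shown. Filled points passed in limma and orange ones lie in shifted segments, among them HSPA5 at -1.02, while TM7SF2 at 0.89 is the one called gene of the cholesterol list above 0.

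Among 26 genes of cholesterol synthesis and uptake 3 fell and 1 rose (6 and 1 over the list alone). The sterol isomerase EBP, in a shifted segment, fell by 0.58 and the squalene epoxidase SQLE fell by 0.47, whereas the sterol reductase TM7SF2 rose by 0.89 ± 0.14 (limma, adjusted p = 0.00121), with a range from 0.586 to 0.973 over the settings. EBP and SQLE lost their calls with median centring (limma, adjusted p = 0.373 and 0.404), without a detection filter and with the replicate number as a block. The list median was -0.34 (camera, adjusted p = 0.000158, and adjusted p = 0.767 with an estimated correlation). The call of SQLE was lost in 11 of 14 fits with 1 tumour left out, and that of EBP without control tumour 1 or 4 or COMP tumour 6 (limma, adjusted p up to 0.086 and 0.0542). In amino acid and one-carbon synthesis 3 of 26 genes fell, both adjusted over all genes and over the list alone. They were PHGDH, in a shifted segment, the proline enzyme PYCR1 by 0.61 and the alanine aminotransferase GPT2 by 0.48 (limma, adjusted p = 0.00108, 0.0232 and 0.0409). PYCR1 lost its call without control tumour 7 or COMP tumour 2 (adjusted p up to 0.0517) and GPT2 in 11 of 14 fits (limma, adjusted p up to 0.0868), and both lost theirs with median centring (limma, adjusted p = 0.233 and 0.395). COMP tumour 7 had the highest GPT2 signal of its group, 8.63.

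Energy metabolism genes were mostly below the threshold. None of 21 glycolysis genes, 19 tricarboxylic acid cycle genes or 27 genes of fatty acid synthesis and oxidation passed, over all genes or over the lists alone. The smallest p values belonged to PFKFB4 (log2 difference -0.34, in a shifted segment), PDHA1 (-0.57, in a shifted segment) and ECHS1 (0.33), with limma adjusted p of 0.117, 0.0546 and 0.0714. PDHA1, PLAUR, CASP9 and ECHS1 passed in some fits with 1 tumour left out or with other settings. LDHA, which makes lactate, differed by 0.06 ± 0.09 (limma, adjusted p = 0.776). Of 54 oxidative phosphorylation genes the complex II subunit SDHA rose by 0.53 and the complex III subunit UQCRC1, in a shifted segment, fell by 0.70 (0 higher and 1 lower over the list alone). SDHA lost its call in 8 of 14 fits with 1 tumour left out (limma, adjusted p up to 0.073), and a further SDHA probe differed by 0.36 and did not pass over all kept probes (limma, adjusted p = 0.0943). SDHA, UQCRC1 and BHLHE40 lost their calls with median centring (limma, adjusted p = 0.0774, 0.0931 and 0.121). Among 23 hypoxia response genes 2 fell, also over the list alone. The carbonic anhydrase CA9 fell by 1.94 ± 0.36 (limma, adjusted p = 0.00345) and the transcription factor BHLHE40 by 0.71, and both lie in shifted segments. BHLHE40 lost its call without control tumour 1 or 2 or COMP tumour 2, 4 or 5 (limma, adjusted p up to 0.0652). The angiogenic factor VEGFA differed by -0.21 ± 0.23 and did not pass (limma, adjusted p = 0.655), with 1 control signal, 8.27 in tumour 1, apart from the others. Camera passed none of these 5 lists over all genes. Without genes of shifted segments the oxidative phosphorylation list passed towards higher expression (camera, adjusted p = 0.0396, and adjusted p = 0.608 with an estimated correlation).

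Among 35 extracellular matrix genes 2 fell (5 over the list alone), the basement membrane collagen COL4A2 by 0.85 ± 0.16 and tenascin-C, TNC, in a shifted segment, by 0.79 ± 0.18 (limma, adjusted p = 0.00333 and 0.0122). The COL4A2 difference ranged from -0.856 to -0.485 over the settings, and TNC lost its call with median centring (limma, adjusted p = 0.103). The list median was -0.20 (camera, adjusted p = 0.0157, and adjusted p = 0.767 with an estimated correlation). The list call was lost without control tumour 7 or COMP tumour 4 (camera, adjusted p = 0.0546 and 0.0945). THBS1, a relative of COMP, differed by -0.33 ± 0.35 (limma, adjusted p = 0.642). None of 24 extracellular proteases and inhibitors passed, also over the list alone, and the urokinase receptor PLAUR had the smallest p (log2 difference 0.58, limma adjusted p = 0.051), with control tumour 5 apart at 10.54. MMP9 was detected in 1 control and 2 COMP tumours and differed by 0.28 ± 0.18 (limma, adjusted p = 0.595), and MMP2 was detected in no tumour.

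In integrins and cell-matrix adhesion, 1 of 32 genes rose and 1 fell (4 and 4 over the list alone), the kinase SRC rising by 0.84 and talin, TLN1, in a shifted segment, falling by 0.37 (limma, adjusted p = 0.0101 and 0.0162). Among 12 epithelial genes 2 rose, keratin KRT19 by 0.92 ± 0.10 and plakoglobin, JUP, by 1.08 ± 0.21 (limma, adjusted p = 5.96e-05 and 0.00498), with 2 higher and 2 lower over the list alone. A further JUP probe differed by 0.57 and did not pass over all kept probes (limma, adjusted p = 0.0589). Of 15 mesenchymal genes TAGLN fell and the ligand WNT5B rose by 0.54 (limma, adjusted p = 0.0177), also over the list alone, and COMP tumour 4 had the lowest WNT5B signal of its group, 7.93. Among 22 genes linked to lung and bone metastasis of this cell line 2 rose and 3 fell, also over the list alone. The actin-bundling fascin, FSCN1, in a shifted segment, rose by 1.03 ± 0.15 (limma, adjusted p = 0.000732), while TNC and IL13RA2 fell and the guidance receptor ROBO1 fell by 0.84, with a range from -0.923 to -0.47 over the settings. With median centring TLN1, WNT5B, TNC and ROBO1 lost their calls (limma, adjusted p = 0.534, 0.106, 0.103 and 0.0748). Camera passed none of these 4 lists.

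Among 17 antigen presentation genes the peptide transporter TAP1 fell by 0.60 ± 0.14 (limma, adjusted p = 0.0191), 1 gene over all genes and 6 over the list alone, and lost its call with median centring (limma, adjusted p = 0.366). The list median was -0.28 (camera, adjusted p = 0.00848, and adjusted p = 0.767 with an estimated correlation), and the list call was lost without control tumour 2 (camera, adjusted p = 0.103). Of 39 interferon response genes 1 rose and 2 fell (4 and 2 over the list alone). IFI6 fell by 0.97 and TAP1 fell as above, while IFIT1 rose by 1.34, a call lost in 10 of 14 fits with 1 tumour left out (limma, adjusted p up to 0.0723), without a detection filter, with an intensity trend and robust estimation and with the replicate number as a block. Of 27 NF-kB targets and cytokines 2 fell, also over the list alone, IL32 by 1.03 and the superoxide dismutase SOD2 by 0.66. Of 21 TGF-beta targets SMAD6 fell by 0.78, BHLHE40 fell and TGIF1 rose by 0.46, also over the list alone. The calls of SOD2 and TGIF1 were each lost in 11 of 14 such fits and that of SMAD6 without COMP tumour 7 (limma, adjusted p up to 0.0982, 0.0842 and 0.0503). The differences of IL32 and SMAD6 ranged from -1.03 to -0.394 and from -0.778 to -0.342 over the settings. SMAD6, SOD2 and TGIF1 lost their calls with median centring (limma, adjusted p = 0.109, 0.348 and 0.164) and without a detection filter (limma, adjusted p = 0.059, 0.1 and 0.0688). Further probes of SOD2 and TGIF1 differed by -0.55 and 0.38 and did not pass over all kept probes (limma, adjusted p = 0.0968 and 0.1785). Camera did not pass the interferon, NF-kB or TGF-beta lists.

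Of 47 cell cycle genes the thymidylate synthase TYMS rose by 0.36 and the kinetochore motor CENPE fell by 0.54, neither passing over the list alone, and the calls were lost in 11 and 10 of 14 fits with 1 tumour left out (limma, adjusted p up to 0.0891 and 0.0952) and with median centring. None of 30 p53 targets and apoptosis genes and none of 22 immediate early genes passed, also over the lists alone, with CASP9 (-0.41) and ATF3 (-0.56) having the smallest p (limma, adjusted p = 0.0587 and 0.1). In calcium handling, 2 of 33 genes rose and 2 fell, also over the list alone. The channel genes TRPC1 and ORAI3 rose by 0.62 each, and the reticulum calcium-binding genes RCN2 and CALU fell by 0.61 and 0.51, CALU losing its call in 9 of 14 such fits (limma, adjusted p up to 0.0751). ORAI3 was detected in 3 of 7 control tumours, and the differences of TRPC1 and ORAI3 ranged from 0.32 to 0.665 and from 0.195 to 0.688 over the settings. ORAI3, RCN2 and CALU lost their calls with median centring (limma, adjusted p = 0.0501, 0.362 and 0.448). Of 51 ribosomal protein genes RPS6, in a shifted segment, fell by 0.47, also over the list alone (limma, adjusted p = 0.0197), a call lost with median centring (limma, adjusted p = 0.395). Camera passed none of these 5 lists.

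Markers of other cell types were examined on the human probes, since the tumours also hold cells of the mouse. Not all lay near background. ESAM, ROBO4, CD14 and HBA1 were detected in all 7 control and all 7 COMP tumours, ESAM with mean log2 signals of 10.41 and 10.83. Whether such signals came from the mouse or from the human cancer cells was not tested. None of the 9 cell type lists passed camera of limma, with the lowest adjusted p, 0.266, for the endothelial list. Among 17 endothelial genes the adhesion molecule ESAM rose by 0.42 and the receptor ROBO4 by 0.83 (2 genes, and 5 higher and 1 lower over the list alone). Among 13 neutrophil genes 1 rose, and among 12 adipocyte genes the complement factor CFD rose by 1.43 ± 0.20 (limma, adjusted p = 0.00166), each also over its list alone. The CFD difference ranged from 0.605 to 1.48 over the settings and that of ROBO4 from 0.499 to 0.893, ROBO4 losing its call with median centring (limma, adjusted p = 0.105) and without background correction (limma, adjusted p = 0.0581). The calls of ESAM and ROBO4 were lost in 9 and 12 of 14 fits with 1 tumour left out (limma, adjusted p up to 0.0806 and 0.0986). No gene passed in the macrophage (20 genes), fibroblast and pericyte (17), skeletal muscle (15), erythroid (11), lymphoid (16) or keratinocyte (13) lists, also over the lists alone. CD14 passed with the detection filter (limma, adjusted p = 0.032) and without control tumour 6 (limma, adjusted p = 0.0392), and DCN with the replicate number as a block. The smallest p values there belonged to CD14 (log2 difference -1.03), DCN (-0.75), TTN (0.20), HBA1 (0.90), MS4A1 and KRT17 (-0.91), with limma adjusted p of 0.0838, 0.147, 0.198, 0.172, 0.356 and 0.431. MS4A1 was detected in 3 control tumours and no COMP tumour, so no size is given for it. Over the settings CD14 ranged from -1.05 to -0.526, DCN from -0.755 to -0.26 and KRT17 from -1 to -0.454. TTN ranged from 0.0386 to 0.199 and HBA1 from 0.465 to 1.01. DCN was detected in 7 control and 2 COMP tumours, with COMP tumour 1 apart at 5.71, and HBA1 was highest in COMP tumour 4 at 11.82.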

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

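The tests of the unfolded protein response genes, including the one without genes of shifted segments, were chosen after those results were seen. So were the tests of the COMP transcript. The exception is the fits leaving out each tumour in turn, which were among the alternatives set beforehand. The splits for the counts of genes and lists and Dixon's criterion were also set beforehand.

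Of 176 groups of 7 values, 12 had a tumour far from the others of its group by Dixon's criterion, where chance gives about 8.8 at 1 in 20. COMP tumour 4 was apart for PHGDH (4.97, lowest), WNT5B (7.93, lowest) and HBA1 (11.82, highest). COMP tumour 1 was highest for EDEM1 (8.05) and DCN (5.71), COMP tumour 3 lowest for WDR72 (6.41) and COMP tumour 7 highest for GPT2 (8.63). Control tumour 5 was highest for EDEM1 (9.31) and PLAUR (10.54), control tumour 2 for ZNF467 (6.38), control tumour 3 for PLD5 (6.33) and control tumour 1 for VEGFA (8.27).

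Chance division of the arrays was excluded for the gene counts and not for the lists. Among 100 splits of the 14 arrays into 7 and 7, 1 split, the real one, gave as many as 467 higher genes and 1 as many as 436 lower genes, and the highest count in either direction among the others was 146. In contrast, 53 splits, the real one included, gave at least 4 pathway lists, with up to 11, so a count of 4 does not mark out the real groups. With 7 tumours per group no split shares them evenly, so the other splits still hold part of the group difference.

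The fall of unfolded protein response genes was weighed against 3 explanations. A single tumour was argued against, since with 1 of the 14 tumours left out the list median stayed between -0.255 and -0.172, and HSPA5, SDF2L1, MANF and EDEM1 kept their limma calls in all 14 fits (the highest camera adjusted p was 8.18e-05). Gene dosage in the shifted chromosome segments stays open. The camera p without those genes was 0.000271, under the bound set for excluding dosage. That bound was wrong because the preset p is not calibrated here, as the splits show (camera, adjusted p = 0.398 with an estimated correlation). Of the 7 genes that fell, 5 lie there, and SDF2L1 lies in a segment whose shift of -0.197 was just short of 0.2. HSPA5 fell by 1.02 in a segment with a median of -0.256, and EDEM1 by 0.71 in one with a median of -0.212. Both falls exceed the regional medians, but these are among the strongest genes of the list and do not stand for all of it. Chance stays open too. The list itself had as small a p in 1 of 100 splits, the real one, but it was singled out as the strongest of 24. In 36 of 100 splits some list had a camera p as small as 3.57e-07, the smallest being 3.39e-16. Lists with a higher estimated correlation enter that count, up to 0.431 against 0.0472 for this list. The count therefore does not measure chance for this list alone. An effect of COMP on these genes remains a hypothesis.

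The COMP transcript near background in 5 of 7 COMP tumours was weighed against mislabelled tumours and a probe outside the transfected sequence. Over the 100 genes with the smallest p in fits without the tumour in question, 14 of 14 tumours lay nearer the mean of their own labelled group. That argues against exchanged labels of single tumours. An exchange of the 2 groups as a whole would give the same result, so the check cannot exclude it. Control tumour 5 was the closest case, with distances of 9.97 to the control and 13.5 to the COMP mean. A probe outside the transfected sequence and a loss of expression in the tumours cannot be told apart, since the deposited tables do not give the probe's place in the gene, and 2 COMP tumours detected it.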

How the results depend on the processing

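Leaving out genes of shifted chromosome segments was chosen after seeing the data, and the other alternatives before. The slide alternative was not run, since the tables give no slide. Median centring gave 185 higher and 99 lower genes, of which 281 were among the 903 calls, and its cause was not tested. A 1.5-fold minimum left 232 and 256, by construction, and leaving out genes of shifted segments left 246 and 195, with 1798 placed genes fewer, and 5 pathway lists passed, oxidative phosphorylation added. With an estimated correlation 0 pathway lists passed. In the other settings the counts stayed within 1.5 times of 467 and 436, from 372 and 309 without a detection filter to 618 and 628 with array weights. The authors' values and no background correction each gave 507 and 436, so these settings are nearly alike. With 1 tumour left out, 332 to 561 genes were higher and 290 to 552 lower. The 290 lower genes came without COMP tumour 2, and the 561 higher and 552 lower genes without control tumour 5. In these fits 3 to 5 pathway lists and 0 cell type lists passed, and the COMP transcript passed in none of them. The COMP transcript passed in no setting, and 0 cell type lists passed in any.

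The replicate numbers did not pair the tumours: correlations of same-numbered tumours ran from -0.05 to 0.115, and 1 of 7 correlated best with its own number. With the replicate number as a block 378 genes were higher and 345 lower, and 653 of the 903 calls were kept. Of 67 named genes past the threshold, 29 kept their call in every setting and with every tumour left out, and none reversed. Dim probes limit the fold changes, since the signal over background is small there.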

Other observations

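All tests in this part were chosen after the result was seen.

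The fall of ACTG2 and TAGLN raised the hypothesis that targets of the actin-regulated factor SRF fell more widely. In a list of 31 other actin cytoskeleton genes and SRF targets 6 fell in limma and none rose. The myosin light chain gene MYL9 fell by 0.99 ± 0.19, the filamin FLNA by 0.70 and the tropomyosin TPM2 by 0.68, and CNN3, PDLIM5 and MYH9 passed too. The list had a camera p of 0.00152 (adjusted p = 0.00368 over 3 lists), and p = 0.0546 (adjusted p = 0.164) with an estimated correlation. The hypothesis of a shared fall therefore stays undecided, and 5 of the 31 genes lie in shifted chromosome segments.

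Besides MAGEC2 and the SPANX genes, the cancer-testis antigen CT83 fell by 1.26 ± 0.21 (limma, adjusted p = 0.00175). In a list of further cancer-testis antigens that left out 7 called genes, CT83 and the SPANX genes among them, 0 of 11 passed in limma. Camera of limma gave that list a p of 0.367 (adjusted p = 0.367), with a median of -0.20, and 6 of the 11 genes lie in shifted chromosome segments. Having left out called genes, the list does not decide whether the family fell together. MT1F, a metallothionein gene that fell by 1.26 ± 0.30, raised the hypothesis of a fall of its metal-binding family. All 6 other members tested had positive differences, with a median of 0.32, and none passed in limma. Camera gave p = 0.00245 towards higher expression (adjusted p = 0.00368), and p = 0.116 (adjusted p = 0.174) with an estimated correlation. A shared fall was thus not seen, and with the estimated correlation the question stays undecided.

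The neighbouring genes that shifted together form the third pattern weighed. None of 100 shuffles of the gene order (0) placed as many genes in shifted segments, the most being 25 against 1798, which argues against a random placement of the changed genes. Background correction and normalization are argued against for the chromosome 7 segment, whose shift was 0.54 and stayed between 0.365 and 0.538 in 3 other sets of values. Among these, the values without background correction and the authors' values were nearly alike, with 943 calls each, and do not count as separate support. A candidate explanation is a difference in DNA copy number between the injected cells of the 2 groups, which the cells may have acquired apart from COMP. The 13 segments found in the odd-numbered tumours had the same sign in the even-numbered ones (100%). However, 1 on the X chromosome had a shift of -1.97e-05 in the even-numbered tumours, where 9 of the 13 were shifted by more than 0.2. In 8 of the 14 segments found over all tumours the groups overlapped, so a difference shared by every tumour of a group is not shown there. In these 8 the control tumours varied more than the COMP tumours. In the X chromosome segment from PLCXD1 to ZXDB, for example, the SD was 0.352 in control and 0.0332 in COMP tumours (n = 7 each). The overlap by itself therefore does not decide for or against a difference in copy number. Comparing odd- with even-numbered tumours does not separate copy number from other regional regulation common to all tumours of a group. DNA was not measured here, and an effect of COMP on these regions was not tested.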
